A study of Mus musculus with 8 samples.

How the data were processed

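The data are gene expression values of 8 mouse skin libraries, 4 from skin treated with MC903 and 4 from skin treated with MC903 plus phytic acid. Per the labels' protocols, total RNA was taken with TRIzol and libraries were made with a SMARTER mRNA-seq kit. Reads were sequenced and processed by the authors, and the deposited table gives 1 FPKM value per gene and library. The submitters' processing notes name cutadapt, HISAT2, TopHat2 and DESeq and the genome build mm10, without saying which tool made the deposited FPKM. Versions, the gene annotation and the strand setting are not given in the sources used here. Overlapping and antisense genes, and close gene copies, therefore have uncertain values. FPKM scales each library to its total, so a large change in a few abundant genes shifts the values of the rest, and alternative scalings were run for that reason.

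The table holds 21959 rows. The 51 rows without a gene name, 0.016% to 0.024% of a column sum, were left out, and for 21 names on more than 1 row the row of highest mean was kept, which left 21885 genes. Columns were matched to samples by the names that the labels give them. The symbols of 21150 genes were found in the GENCODE annotation of GRCm38, the assembly that mm10 names, and coordinates are from there, counted from 1. The deposited FPKM values were close to whole reads when multiplied by exon length. Of 17982 genes with a value and a single record in that annotation, 17509 (97.4%) came out within 0.05 of whole numbers in all libraries. This gave the library totals, 31676934 to 42997271 reads, which set the depth of each value. Replicates of a group differed by far more than counting noise (chi-square per gene of 45.4 to 200), so the columns hold separate libraries.

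Values were analysed as log2(FPKM + 1), so that fold changes of low genes are understated. The 12165 genes with an FPKM of at least 1 in at least 4 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with group as the single factor. All tests are two-sided and a call is an adjusted p (Benjamini-Hochberg) under 0.05. Each log2 fold change is MC903 plus phytic acid minus MC903. Means and SDs are of FPKM over 4 libraries per group. A lenient count took genes with an unadjusted p under 0.05 and a change of at least 2-fold. Lists were tested with camera at a preset correlation of 0.01, again with a correlation estimated per list, and with fry, which asks whether the members of a list change without comparing them with other genes.

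The gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the other settings tried, apart from those given below as chosen later. The 36 lists cover cornified envelope, late cornified envelope, wound and hyperproliferation, basal keratinocyte, barrier lipid, cholesterol and fatty acid synthesis, and junction genes. They cover type 2, type 17, interferon and antimicrobial genes, and genes of the aryl hydrocarbon receptor, pregnane X receptor, oxidative stress, vitamin D, inositol phosphate and histone deacetylases, cell cycle and matrix. The others are markers of T cells, mast cells, eosinophils, neutrophils, macrophages, Langerhans and dendritic cells, B cells, hair follicle, sebaceous gland, adipocytes, skeletal muscle, melanocytes, endothelium, nerve, cartilage and blood, and signs of dissection stress and RNA quality. Of these, 32 had at least 5 tested members and were tested as lists. The rule named, per direction, the 10 called genes of largest change whose groups did not overlap, and per list up to 3 called members of smallest p, or 2 members where none was called. Lists of other cell types and of RNA quality were named so only if the list or a member was called. It always named Flg, Lor, Ivl, Tslp, Il4, Il13, Il33, Cyp1a1, Ahr, Cyp24a1, Hdac3, Krt16 and S100a8. It gave 112 genes, of which those with calls that hinge on a single library are mostly given by their list's count. Symbols of predicted genes were counted and not named.

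The procedure was tested on simulated data with 11660 genes, drawn 20 times with 200 changed genes. It called 30.1% of genes changed 1.5-fold, 64.9% of those changed 2-fold and 92.4% of those changed 4-fold, and 6.1% of its calls were unchanged genes. Genes were drawn independently and few were changed, whereas 25.8% of tested genes were called in the real data. These rates may therefore not carry over to the real comparison. Alternatives were other pseudocounts (0.1 and 0.01), no filter, a mean FPKM of at least 5, scaling to TPM, median-of-ratios scaling, quantile normalization, library weights, eBayes without trend or robust, the replicate number as a block, and leaving out each library. Alternatives chosen after seeing the data were limma voom on the recovered reads, thinning to equal depth, centring on basal keratinocyte genes and list counts without each library. A negative binomial model was not fitted to the recovered reads. Single scores in the closing part were tested by exact permutation of the 70 assignments of 4 against 4, whose smallest two-sided p is 0.0286. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.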

Results

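Gene expression was measured by RNA sequencing in 8 libraries of mouse skin. The skin had been treated with MC903 alone in 4 libraries, titled control by the submitters, and with MC903 plus phytic acid in the other 4. MC903 is calcipotriol, a vitamin D analogue that brings about an inflammation resembling atopic dermatitis when it is put on mouse skin. Phytic acid is inositol hexaphosphate, the phosphate store of plant seeds. The series concerns the effect of phytic acid on the skin barrier in atopic dermatitis models, and the design gives the comparison of MC903 plus phytic acid with MC903 alone. Neither group was untreated skin, so each value below is relative to MC903 skin. The values were deposited as FPKM (fragments per kilobase of gene, scaled to the library total). The library totals recovered from them were 31676934, 32048847, 37639476 and 37392670 reads for MC903 replicates 1 to 4. They were 40746578, 38310034, 42997271 and 40781490 for MC903 plus phytic acid, so that each phytic acid library was deeper than each MC903 library. The labels do not say whether the libraries came from separate mice, and the p-values measure the spread between these samples, which may be technical.

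With phytic acid, skin had far less RNA of the epidermal alarm cytokine Tslp, of the vitamin D target Cyp24a1 and of the wound keratins Krt6a, Krt6b and Krt16. It had far more RNA of the suprabasal keratin Krt77, of Lor (loricrin, a main protein of the cornified envelope) and of major histocompatibility class II genes. Krt77 rose from a mean FPKM of 27.4 ± 32.6 (SD, n = 4) to 1379 ± 142 (SD, n = 4), a log2 fold change of 6.38 ± 0.70 (SE). Tslp fell from 765 ± 452 to 20.9 ± 16.1, a log2 fold change of -5.30 ± 0.64. Of 12165 genes tested, 3134 (25.8%) were called at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment, 1722 higher and 1412 lower with phytic acid. Among the called genes, 385 were at least 2-fold higher and 313 at least 2-fold lower, and 58 and 98 at least 4-fold. The values of the groups did not overlap for 3322 of the 12165 genes tested, against the 2.86% of genes that chance gives. Without MC903 replicate 1, 2013 genes were called, 1072 higher and 941 lower, and weighting each library by its quality gave 4796 calls. The balance turned with median-of-ratios scaling (1584 higher and 1712 lower) and quantile normalization (1652 and 1748). Centred on basal keratinocyte genes, an alternative chosen after seeing the data, the split was 1817 higher and 549 lower, with a median log2 fold change of all genes of 0.22 against 0.05.

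**Figure D1:**
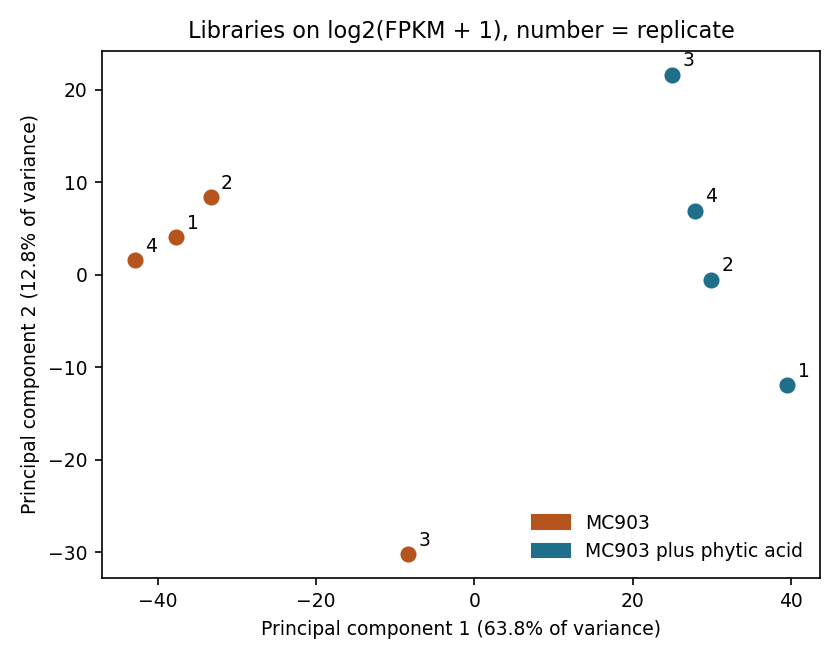
Principal component 1 (horizontal axis, 63.8% of the variance) against principal component 2 (vertical axis, 12.8%) of log2(FPKM + 1) over the 12165 tested genes, with 1 point per library and the replicate number beside it. The 4 phytic acid libraries lie between 24.9 and 39.5 on component 1 and MC903 replicates 1, 2 and 4 between -42.8 and -33.3, while MC903 replicate 3 lies at -8.41 and, on component 2, at -30.2.

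The largest rises after Krt77 were those of Lce1m (log2 fold change 4.27 ± 0.51, SE), a late cornified envelope gene, Skint9 (3.77 ± 0.72), Mup22 (3.68 ± 0.77), Skint7 (3.64 ± 0.26), Dapl1 (3.57 ± 0.78), the epidermal lipoxygenase gene Alox12e (3.40 ± 0.60), Mrgprb3 (3.34 ± 0.23), Mybph (3.27 ± 0.30) and Skint6 (3.15 ± 0.52). Skint genes encode butyrophilin-like proteins of the skin and thymus. Mup22 was uneven, at a mean FPKM of 27.5 ± 30.3 (SD, n = 4) with phytic acid and 0.419 ± 0.750 without. The largest falls after Tslp were those of the collagenase gene Mmp13 (-4.99 ± 0.73), trichohyalin (Tchh, -4.67 ± 0.22), Krt6b (-4.58 ± 0.58), Cstdc6 (-4.37 ± 0.43), Akr1d1 (-4.34 ± 0.40), Cyp24a1 (-4.29 ± 0.49), Csta3 (-4.28 ± 0.78), Myl7 (-4.18 ± 0.57) and Stfa2 (-4.02 ± 0.52). In the GRCm38 annotation, the assembly that mm10 names, Krt77 spans 101858731 to 101869705 on chromosome 15 and Tslp 32815383 to 32819797 on chromosome 18. Cyp24a1 spans 170482708 to 170497145 on chromosome 2, and Krt16 spans 100246091 to 100248902 on chromosome 11. All 4 are protein-coding genes, and their values are sums over exons. Members of the Skint, Mup, stefin (Stfa, Cstdc, Csta), Sprr2, Lce and Krt6 families have close copies in the genome. How reads shared between such copies were counted is not given in the sources used here, so values of single members are uncertain.

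Genes of wounded and hyperproliferating keratinocytes fell together. Of 22 tested members of this list, 20 fell and 0 rose, and 22 were lower when adjusted over the list alone, with a median log2 fold change of -2.70. Krt6a went from 891 ± 434 FPKM (SD, n = 4) to 53.1 ± 26.0, Krt16 from 2302 ± 679 to 159 ± 98.8, and the growth factor gene Areg (amphiregulin) from 29.3 ± 10.03 to 3.72 ± 1.77. The camera test gave an adjusted p of 1.71e-15 for the list with the preset correlation and an adjusted p = 0.474 with an estimated correlation. With 1 library left out, 17 to 21 members fell. Cell cycle genes were lower in the same libraries: 15 of 26 fell and 0 rose (20 lower adjusted over the list alone), with a median of -0.55 and an adjusted p of 4.53e-09 by camera, or adjusted p = 0.655 with an estimated correlation. The replication helicase genes Mcm5 (log2 fold change -1.63 ± 0.17, SE) and Mcm2 (-0.99 ± 0.15) and the nucleotide reductase gene Rrm2 (-1.16 ± 0.17) led these. Centred on basal keratinocyte genes, 6 cell cycle members fell. Skeletal muscle markers were higher in the same libraries, with a median of 1.01.

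**Figure D2:**
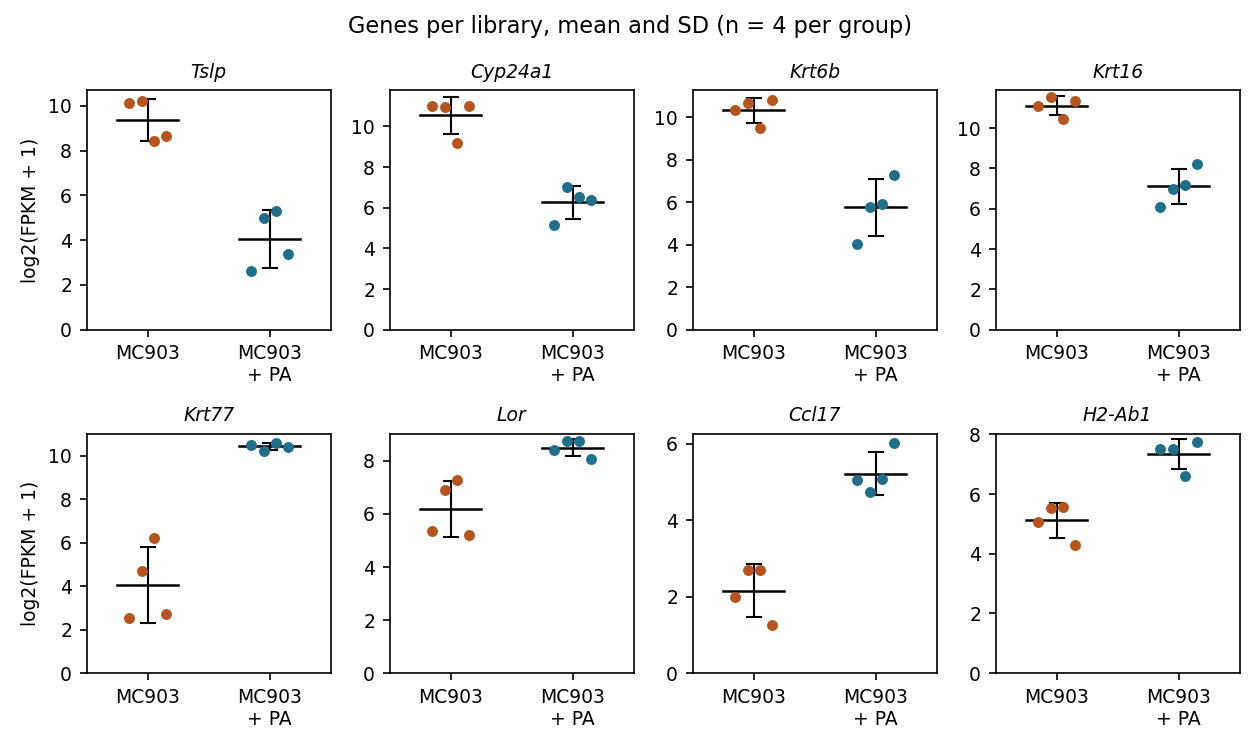
FPKM of 8 genes per library, on the vertical axis as log2(FPKM + 1), in MC903 skin (left in each panel) and MC903 plus phytic acid skin (right), with 1 point per library, a horizontal line at the mean and bars of 1 SD (n = 4). Tslp, Cyp24a1, Krt6b and Krt16 are lower and Krt77, Lor, Ccl17 and H2-Ab1 higher in each phytic acid library than in each MC903 library.

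Vitamin D response genes contained the strongly lowered Cyp24a1, the enzyme that breaks down active vitamin D and that vitamin D receptor ligands induce. It stood at 2066, 2008, 585 and 2056 FPKM in MC903 replicates 1 to 4, and at 34.2, 127, 89.6 and 83.2 with phytic acid. Of 8 tested members, 3 fell and 0 rose (4 lower adjusted over the list alone), with a median log2 fold change of -0.77 (-0.43 without MC903 replicate 2 and -0.44 without a filter). Spp1 (osteopontin) was another, at 24.4 ± 14.9 FPKM (SD, n = 4) against 6.97 ± 1.95. Camera gave the list an adjusted p of 0.0408, and adjusted p = 0.557 with an estimated correlation. The call was lost without MC903 replicate 2 (0.0739), phytic acid replicate 1 (0.0685) or phytic acid replicate 4 (0.0506). It was also lost without a filter (0.0668), with a mean FPKM of at least 5 (0.0930), and with median-of-ratios (0.0712) or quantile scaling (0.0846).

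Cornified envelope genes moved both ways. Of 29 tested members, 10 rose and 9 fell (14 and 10 adjusted over the list alone). Lor rose from 87.6 ± 59.0 FPKM (SD, n = 4) to 367 ± 79.9, and Flg2 (filaggrin 2) from 13.1 ± 6.42 to 82.0 ± 16.6. Ivl (involucrin) rose from 32.7 ± 24.3 to 90.7 ± 27.7. The adjusted p of Ivl by limma was 0.0184 with all libraries, 0.0551 without MC903 replicate 1 and 0.0502 without phytic acid replicate 1. Flg (filaggrin) stood at 47.1 ± 13.6 and 62.1 ± 26.5, and its log2 fold change of 0.34 ± 0.31 (SE) did not pass (adjusted p = 0.463 by limma). Rptn (repetin) fell from 1846 ± 735 to 149 ± 21.9 and the transglutaminase gene Tgm3 from 24.7 ± 5.51 to 5.95 ± 0.831. The list as a whole was not called by camera (adjusted p = 0.813). Its median (0.34) and mean (0.29) were above 0 and the direction of the test was down. Without MC903 replicate 1, 5 members rose.

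Late cornified envelope genes moved both ways. The 6 called lower were Lce3a to Lce3f, which are known to be induced in injured skin, while the 6 called higher were 5 Lce1 genes and Lce6a, out of 21 tested, and the other 9, all Lce1 genes, were not called (7 higher and 6 lower adjusted over the list alone). Lce3d went from 88.8 ± 61.6 FPKM (SD, n = 4) to 5.43 ± 3.67 and Lce3c from 52.2 ± 28.6 to 6.21 ± 1.77, whereas Lce1m went from 14.1 ± 12.5 to 229 ± 64.6. The count of higher members was 2 or 3 without any 1 of MC903 replicates 1 and 4 and the 4 phytic acid libraries. The median of the family was -0.19 and camera did not call it (adjusted p = 0.533), except centred on basal keratinocyte genes (0.0313). Basal keratinocyte genes also moved apart, with 2 of 12 higher, 3 lower, a median of -0.13 and no call by camera (adjusted p = 0.533). Adjusted over the list alone, 3 were higher and 4 lower. Krt15 rose from 119 ± 39.1 to 459 ± 46.1, Krt14 fell from 5275 ± 1619 to 1357 ± 254, and Dst (dystonin) rose by a log2 fold change of 0.63 ± 0.11 (SE).

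The list of cholesterol and fatty acid synthesis genes moved unevenly. Those that fell were mainly genes of cholesterol synthesis, and no tested gene of fatty acid synthesis was called. Of 22 tested members 13 fell and 0 rose (13 adjusted over the list alone), with a median log2 fold change of -0.64. Sqle (squalene epoxidase) fell from 51.7 ± 3.01 FPKM (SD, n = 4) to 26.5 ± 3.02 and Lss (lanosterol synthase) from 15.2 ± 1.48 to 6.48 ± 1.03. Camera gave an adjusted p of 3.22e-07, and adjusted p = 0.557 with an estimated correlation. The mean log2(FPKM + 1) of the list overlapped between the groups (exact permutation p = 0.0571), with phytic acid replicate 1 (5.24) above MC903 replicate 2 (5.22). Centred on basal keratinocyte genes, 7 members fell. Markers of skeletal muscle (median 1.01), adipocytes (1.16) and nerve (0.51) were higher in the same libraries. Genes of barrier lipid synthesis and secretion went both ways, with 7 of 29 higher, 9 lower, a median of -0.14 and no call (adjusted p = 0.309). Adjusted over the list alone, 8 were higher and 11 lower. The epidermal lipase genes Lipn (1.49 ± 0.16, SE) and Lipk (1.58 ± 0.20) rose, and Degs2, a sphingolipid desaturase and hydroxylase gene, fell (-1.70 ± 0.21). Centred on basal keratinocyte genes, 6 barrier lipid genes rose and 3 fell, with a median of 0.04. The count of higher barrier lipid genes was 4 without MC903 replicate 1, MC903 replicate 4 or phytic acid replicate 2. Of 24 tight junction and desmosome genes, 6 rose and 10 fell (7 and 11 adjusted over the list alone), with a median of -0.20 and an adjusted p of 0.0620 by camera. The desmosome genes Dsg3 (-1.09 ± 0.11), Dsc2 (-1.59 ± 0.18) and Pkp3 (-0.92 ± 0.11) were among those that fell. This list was called without MC903 replicate 1 (0.0387), MC903 replicate 4 (0.0435), phytic acid replicate 2 (0.0430) or phytic acid replicate 3 (0.0301). It was also called without a filter (0.0397), with a mean FPKM of at least 5 (0.0233), by voom (0.0306), at equal depth (0.0349) and centred on basal keratinocyte genes (0.0400, with 6 lower).

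Type 2 inflammation genes did not move as a group (camera adjusted p = 0.806), although 7 of 27 rose and 4 fell (8 and 5 adjusted over the list alone). Tslp, Il33, another alarm cytokine of keratinocytes, and Areg fell. Ccl17, a chemokine that draws T helper 2 cells, rose from 3.84 ± 2.02 FPKM (SD, n = 4) to 38.6 ± 17.2. Il33 went from 55.2 ± 18.5 to 14.3 ± 3.23. Il4 was low in both groups, at 1.67 ± 0.461 and 1.83 ± 0.851 (adjusted p = 0.875 by limma), and Il13 was below the expression filter. The median of the list was 0.18. Without MC903 replicate 4, 3 members rose, and 4 rose without MC903 replicate 2 or phytic acid replicate 1. Of 18 type 17 and innate inflammation genes, 4 fell and 0 rose (4 adjusted over the list alone), with a median of -0.65 (-0.33 without MC903 replicate 4, -0.42 and -0.39 without phytic acid replicates 1 and 2, -1.27 by voom). Ptgs2 (cyclooxygenase 2) fell from 39.5 ± 29.9 to 1.46 ± 0.556. Camera gave an adjusted p of 0.0432, and adjusted p = 0.848 with an estimated correlation. This call was lost without MC903 replicate 2 (0.111), MC903 replicate 4 (0.124), phytic acid replicate 1 (0.109) or phytic acid replicate 2 (0.270), and with a mean FPKM of at least 5 (0.366), median-of-ratios (0.108) or quantile scaling (0.121), voom (0.0636) or equal depth (0.0758). Without MC903 replicate 3, 7 members fell and 1 rose, and 2 fell without MC903 replicate 1 or any 1 of the 4 libraries that ended the call.

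Of 17 antimicrobial genes, 8 fell and 4 rose (11 and 4 adjusted over the list alone), with a median log2 fold change of -1.49. The protease inhibitor gene Slpi fell from 74.7 ± 43.3 FPKM (SD, n = 4) to 3.43 ± 2.17 and Wfdc12 from 18.1 ± 10.6 to 1.15 ± 0.516, while the beta-defensin gene Defb6 rose from 281 ± 32.9 to 732 ± 152. S100a8, a calprotectin subunit gene, went from 132 ± 121 to 28.0 ± 27.0. Its adjusted p by limma was 0.0473, and it was 0.0861 without MC903 replicate 1, 0.0794 without MC903 replicate 2, 0.117 without MC903 replicate 4, 0.113 without phytic acid replicate 1 and 0.121 without phytic acid replicate 2. For the list, camera gave an adjusted p of 0.0435, and adjusted p = 0.748 with an estimated correlation. The call of the list was lost without MC903 replicate 1 (0.0667), MC903 replicate 2 (0.0829), phytic acid replicate 1 (0.0947) or phytic acid replicate 2 (0.102), and with a mean FPKM of at least 5 (0.120), median-of-ratios (0.116) or quantile scaling (0.140) or voom (0.0881). In this list, 5 members fell without MC903 replicate 1, 2 or 4 or phytic acid replicate 2. Of 23 interferon response genes, 2 rose (Ifit2 and Ifit3) and 0 fell, 0 were called adjusted over the list alone, the median was 0.41, and camera did not call them (adjusted p = 0.0525). That test lay close to the threshold: the list was called with pseudocounts of 0.1 (0.0386) and 0.01 (0.0367), median-of-ratios scaling (0.0352), library weights (0.0307), a replicate block (0.00421) and basal centring (0.00964, with 8 higher). Without MC903 replicate 4, 11 interferon genes were higher with an adjusted p of 2.81e-07 for the list, and without phytic acid replicate 3 5 were higher (0.0157). The list also passed without phytic acid replicate 2 (0.0430), where 0 were higher, as without MC903 replicate 2, and 1 was higher without MC903 replicate 1 or phytic acid replicate 1 or 4.

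Markers of antigen-presenting cells were higher with phytic acid, as were those of skeletal muscle (median log2 fold change 1.01), adipocytes (1.16) and nerve (0.51) in the same libraries. Of 13 Langerhans and dendritic cell markers, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 fold change of 1.08 (1.94 by voom). The class II genes H2-Ab1, H2-Aa and H2-Eb1 rose from 35.9 ± 13.1, 41.3 ± 15.05 and 47.5 ± 19.4 FPKM (SD, n = 4) to 168 ± 49.8, 178 ± 52.1 and 223 ± 68.5. Camera gave an adjusted p of 1.0e-04, and adjusted p = 0.557 with an estimated correlation. T cell markers rose in 7 of 8 tested members and fell in 0 (8 higher adjusted over the list alone), with a median of 0.77 and an adjusted p of 0.00249, or adjusted p = 0.748 with an estimated correlation. Cd3g, a subunit of the T cell receptor complex, went from 1.21 ± 0.681 to 5.86 ± 1.88. These genes are low, and 1 to 3 T cell markers were called without any 1 of MC903 replicates 1 and 4 and phytic acid replicates 1, 2 and 4. Of 14 macrophage and monocyte markers, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.19 and no call (adjusted p = 0.533). Ccr2, a monocyte chemokine receptor gene, rose (1.73 ± 0.30, SE), as did Lyz2 (0.89 ± 0.17). The count of higher macrophage markers was 2 without MC903 replicate 2, MC903 replicate 4, phytic acid replicate 1 or phytic acid replicate 4, and 2 fell without MC903 replicate 3.

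Mast cell and basophil markers were not called as a group (adjusted p = 0.621, median -0.04), with 1 of 13 higher and 2 lower (1 and 2 adjusted over the list alone). Mrgprb2, a receptor of mast cells, rose from 2.60 ± 0.318 FPKM (SD, n = 4) to 7.43 ± 1.05, and Fcer1a, part of the IgE receptor, fell from 12.8 ± 7.56 to 3.73 ± 0.173. Without MC903 replicate 1 or 4 or phytic acid replicate 1 or 4, 1 fell. Only 2 eosinophil markers passed the filter, and both rose, Ear2 from 27.2 ± 14.2 to 127 ± 52.5 and Ear6 from 0.461 ± 0.448 to 2.94 ± 1.26. Of 6 neutrophil markers, 1 rose (Il1r2, 1.32 ± 0.21, SE) and 2 fell, with a median of -0.32 and no call (adjusted p = 0.533; 1 and 2 adjusted over the list alone). Without MC903 replicate 1, 2 or 4, 1 neutrophil marker fell, and 0 fell without phytic acid replicate 1 or 2. The single tested B cell and immunoglobulin marker, Jchain, was called higher with all libraries (adjusted p of 0.0432 by limma). It was not called without MC903 replicate 2 (0.110), 3 (0.0723) or 4 (0.0863) or phytic acid replicate 1 (0.106), 2 (0.0543) or 4 (0.104).

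Genes of the aryl hydrocarbon receptor pathway were not called as a group (camera adjusted p = 0.999, median -0.05). Of 12 tested, 3 rose and 2 fell (3 and 2 adjusted over the list alone). Ahr itself rose from 11.9 ± 2.35 FPKM (SD, n = 4) to 27.1 ± 3.19 and Aldh3a1 from 19.7 ± 3.39 to 59.3 ± 13.2, while Nqo1 fell from 18.8 ± 7.15 to 7.47 ± 1.21. Cyp1a1, the classical target of the receptor, stood at 8.64 ± 2.27 and 6.97 ± 2.72 (adjusted p = 0.400 by limma). The direction of the test was up, while the median and the mean (-0.01) were below 0, and 1 member fell without MC903 replicate 1. The fry test, which does not compare a list with other genes, gave an adjusted p of 0.0422 in the direction up. Of 6 pregnane X receptor genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with a median of 0.24 and no call (adjusted p = 0.397). Gstm1 rose in this list (0.78 ± 0.12, SE), and the receptor gene itself, Nr1i2, was below the filter. With 1 library left out, 1 pregnane X receptor gene rose in all cases but that of MC903 replicate 1, and 0 fell without MC903 replicate 1, 2 or 4 or phytic acid replicate 4. Oxidative stress genes were not called as a group by camera (adjusted p = 0.174, median -0.11; 0.0267 centred on basal keratinocyte genes, 0.0422 by fry), with 4 of 18 higher and 6 lower (4 and 7 adjusted over the list alone). Gpx2 (-1.14 ± 0.12) and Slc7a11 (-1.63 ± 0.21) fell and Gsta2 (1.84 ± 0.21) rose.

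Genes of inositol phosphate metabolism and class I histone deacetylases, 21 tested, were 2 higher and 2 lower (2 and 2 adjusted over the list alone) and were not called as a group (adjusted p = 0.533). Itpk1 fell from 12.3 ± 2.496 FPKM (SD, n = 4) to 5.02 ± 0.812 and Ippk, which encodes the kinase that makes inositol hexaphosphate, from 9.80 ± 2.34 to 5.13 ± 0.469, while Itpkb rose from 8.72 ± 2.28 to 16.7 ± 0.932. Hdac3 stood at 19.1 ± 0.770 and 17.01 ± 0.606, and its log2 fold change of -0.16 ± 0.08 (SE) did not pass (adjusted p = 0.152 by limma). The median of this list was 0.02, while its mean (-0.04) was below 0 and the direction of the test was down. Without MC903 replicate 1, 2 or 4 or phytic acid replicate 1 or 2, 1 member rose.

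Markers of tissue beneath the epidermis moved with the groups. Of 21 skeletal muscle markers, 17 rose and 0 fell (19 adjusted over the list alone), with a median log2 fold change of 1.01. The fast muscle genes Mylpf and Myl1 rose from 199 ± 43.4 and 101 ± 13.0 FPKM (SD, n = 4) to 898 ± 274 and 398 ± 105.4. Camera gave an adjusted p of 6.25e-09, and adjusted p = 0.391 with an estimated correlation. Of 13 adipocyte markers 4 rose and 0 fell (5 adjusted over the list alone), with a median of 1.16 (0.70 without MC903 replicate 1 and 0.77 without phytic acid replicate 2), an adjusted p of 0.0240 and adjusted p = 0.748 with an estimated correlation. Car3 rose from 70.2 ± 51.6 to 406 ± 202, Cfd (adipsin) from 173 ± 103 to 532 ± 140 and Adipoq (adiponectin) from 16.9 ± 14.6 to 72.9 ± 40.4. Without MC903 replicate 3, 7 adipocyte markers rose, and without phytic acid replicate 2 1 adipocyte and 1 muscle marker fell. Of 10 nerve and Schwann cell markers, 6 rose and 0 fell (7 adjusted over the list alone), with a median of 0.51, an adjusted p of 0.00252 and adjusted p = 0.557 with an estimated correlation. By contrast, 0 of 15 endothelial markers were called by limma (median -0.02, 0 adjusted over the list alone, camera adjusted p = 0.729), while 2 were lower without MC903 replicate 3 and 1 was higher without phytic acid replicate 3. Of 24 extracellular matrix and fibroblast genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone), with a median of 0.25 and no call (adjusted p = 0.533). Dpt (dermatopontin, 1.33 ± 0.22, SE) and Fn1 (fibronectin, 1.09 ± 0.24) rose and Mmp13 fell. The counts of this list ran from 1 to 7 when 1 library was left out: 7 rose without phytic acid replicate 3 and 5 without MC903 replicate 3, while 1 fell without MC903 replicate 1, MC903 replicate 4, phytic acid replicate 1 or phytic acid replicate 4.

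**Figure D3:**
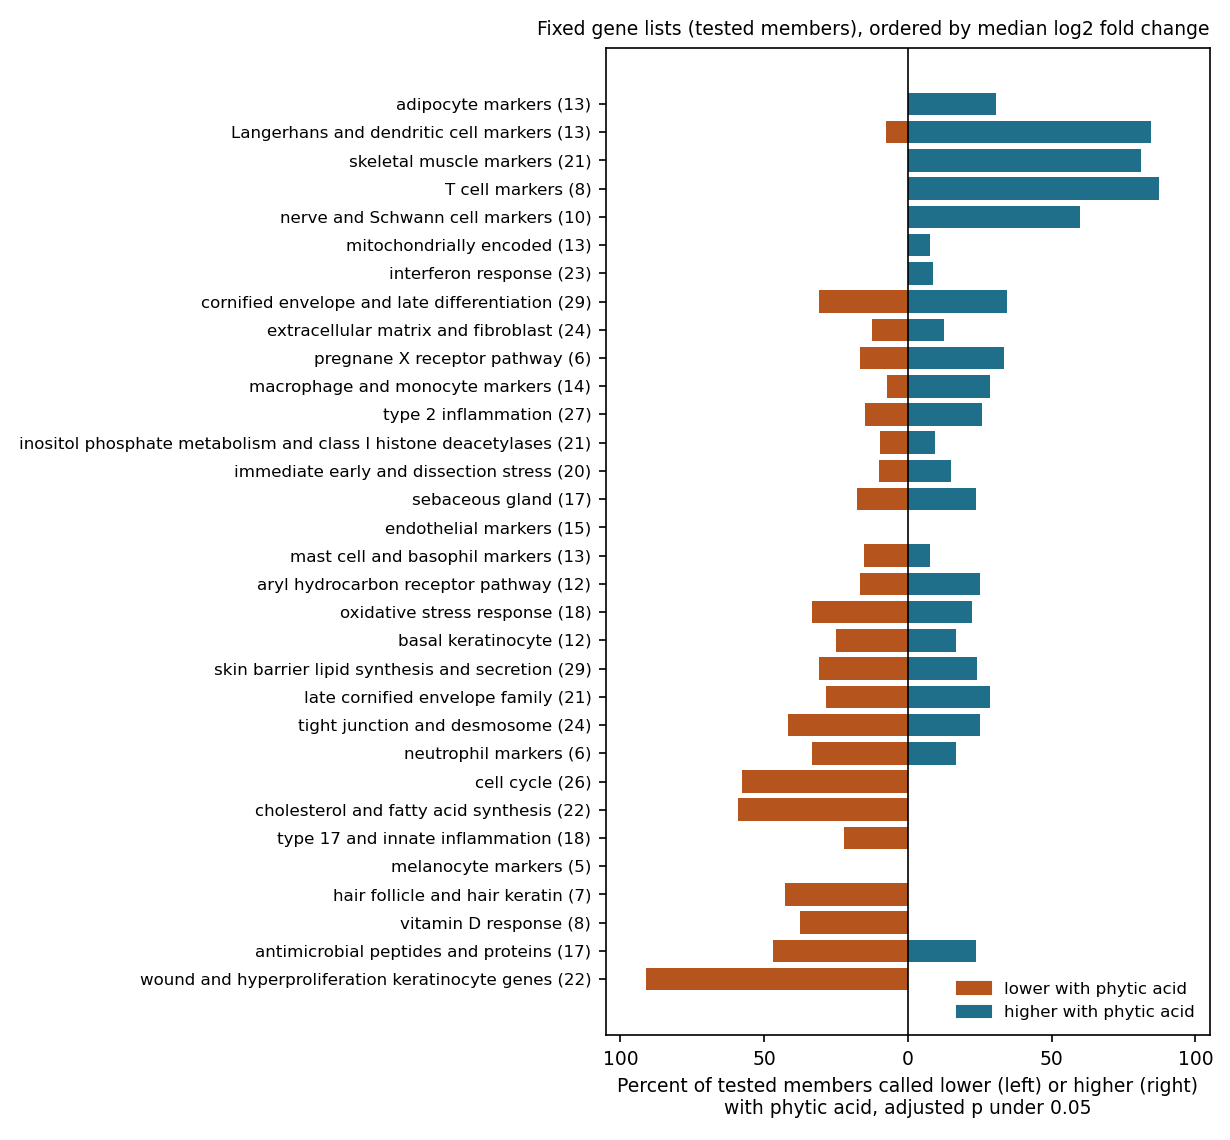
Share of the tested members of each of 32 fixed gene lists (vertical axis, with the number tested) that were called lower (left) or higher (right) with phytic acid at an adjusted p under 0.05, in percent (horizontal axis). Lists are ordered by their median log2 fold change, with wound and hyperproliferation genes (20 of 22 lower) at the bottom and, at the top, Langerhans and dendritic cell (11 of 13 higher) and skeletal muscle markers (17 of 21 higher) next to adipocyte markers.

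Of 7 tested hair follicle genes, 3 fell and 0 rose (3 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.75, an adjusted p of 0.0408 by camera and adjusted p = 0.848 with an estimated correlation. Tchh and the hair transcription factor gene Hoxc13 (16.9 ± 6.59 FPKM against 2.52 ± 0.671, SD, n = 4) fell. Without MC903 replicate 3, 3 rose and 3 fell, the median was -0.24 and the call of the list was lost (0.177), as it was without phytic acid replicate 4 (0.0519) and with median-of-ratios (0.0712) or quantile scaling (0.0697) or library weights (0.141). The other 22 members with a value above 0, most of them hair keratin genes, were below the expression filter, and each was highest in MC903 replicate 3. Krt71, a keratin of the inner root sheath, stood at 1373 FPKM there, at 22.3 in MC903 replicate 2 and at no more than 0.135 in the other 6 libraries. Melanocyte markers behaved alike: their mean log2(FPKM + 1) was 4.07 in MC903 replicate 3 and between 1.51 and 1.91 in the other 7 libraries. By limma, 0 of 5 were called (median -0.65, or 0.05 without MC903 replicate 3, 0 adjusted over the list alone, camera adjusted p = 0.533).

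**Figure D4:**
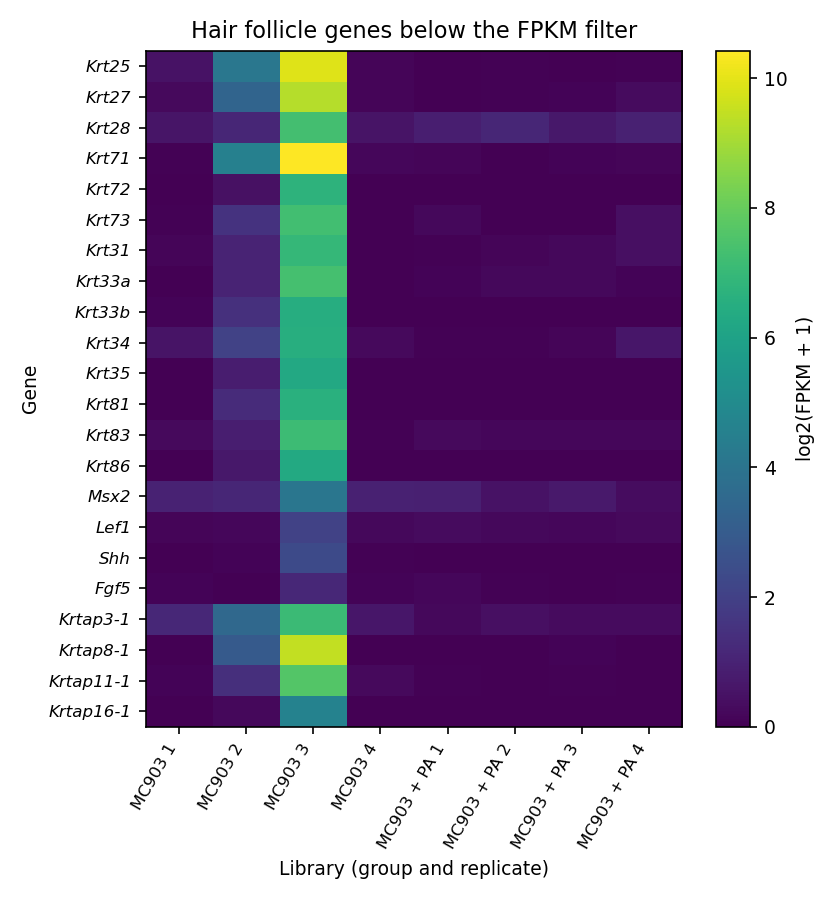
log2(FPKM + 1), as colour, of the 22 hair follicle genes below the expression filter (vertical axis) in each library (horizontal axis). All 22 are highest in MC903 replicate 3, and Krt71 reaches 1373 FPKM there.

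Sebaceous gland genes were not called as a group (adjusted p = 0.800, median -0.01). Of 17, 4 rose and 3 fell (5 and 3 adjusted over the list alone), among them Krt79 (1.07 ± 0.11, SE), which rose, and Fabp5 (-2.41 ± 0.21) and Elovl3 (-1.28 ± 0.18), which fell. Fabp5 is also expressed in epidermal keratinocytes. The count of higher sebaceous genes was 2 without MC903 replicate 4, phytic acid replicate 2 or phytic acid replicate 3. The single tested cartilage marker and the 3 tested blood and hemoglobin genes were not called (0 by limma, medians 0.55 and 0.02; the mean of the blood genes was -0.06), although the cartilage marker rose without MC903 replicate 3. Of 20 immediate early and dissection stress genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone), with a median of -0.01, a mean of 0.06 and no call (adjusted p = 0.682, direction down). Egr3 fell (-0.86 ± 0.11), and Atf3 (1.97 ± 0.46) and Egr2 (0.78 ± 0.18) rose. Without MC903 replicate 3, 4 of them fell, and 1 fell without any 1 of MC903 replicates 1, 2 and 4 and phytic acid replicates 1 to 3. Of 13 mitochondrially encoded genes, 1 rose, mt-Co3, from 49.7 ± 7.67 to 103 ± 37.1 FPKM (SD, n = 4), and 0 fell (1 adjusted over the list alone). Their median was 0.42, with an adjusted p of 0.0435 by camera and adjusted p = 0.848 with an estimated correlation. The call of this list was lost without MC903 replicate 3 (0.214), MC903 replicate 4 (0.124), phytic acid replicate 1 (0.0685) or phytic acid replicate 3 (0.188), and without a filter (0.114), with median-of-ratios scaling (0.0816), library weights (0.263) or basal centring (0.0948). In this list, 2 rose without phytic acid replicate 2. Skeletal muscle markers were also higher with phytic acid (17 of 21, median 1.01).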

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

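The tests of the patterns below were chosen after the result was seen, except the count of hair follicle genes below the expression filter, which was set before those genes were looked at. The 8 libraries can be split into 4 and 4 in 35 ways. The real split gave 3134 called genes, and the highest of the others gave 0. A share of 1 of 35 is the smallest possible. The other splits mix the groups, which adds the group difference to their spread and lowers their counts. Chance is therefore argued against, though not excluded, for the number of called genes. The same holds for the 726 genes with an unadjusted p under 0.05 and at least a 2-fold change. That count was reached by 1 of 35 splits, with 323 in the highest other. Chance is not argued against for the number of gene lists called by camera: 14 of the 35 splits gave 13 or more, the highest other 19. All splits used the preset correlation. With a correlation estimated per list, the real split gave 0 called lists, and the other splits were not run that way. List calls at the preset correlation alone therefore do not argue against chance, and the cause was not tested.

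Of 288 groups of 4 values looked at, 17 held a library far from the other 3, where chance alone gives about 14.4. MC903 replicate 3 was that library in 9 of the 17. On the log2(FPKM + 1) scale it was high in Mup22 (1.35), Itpkb (3.71), Padi3 (5.64) and Egr2 (4.70), and in the means of the hair follicle (5.17) and melanocyte (4.07) lists. It was low in Cstdc6 (5.24), Cyp24a1 (9.20) and Ippk (2.88). MC903 replicate 4 was high in Mcm2 (2.80) and in the mean of the interferon response list (3.12). MC903 replicate 2 was low in the mean of the cholesterol and fatty acid synthesis list (5.22). Phytic acid replicate 3 was high in Lipn (4.77) and low in Dsc2 (1.85) and Cd4 (1.14). Phytic acid replicate 4 was low in Cyp3a13 (2.105) and high in Fabp5 (8.201).

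MC903 replicate 3 stood apart, between the groups on the first principal component. A mixture with, or a swap for, a phytic acid library of this series is argued against as the cause: Krt77 (74.2 FPKM there, at least 1195 in each phytic acid library) allows a share of at most 6.21%, while Cyp24a1 would need at least 72.1% if the rest were like the other MC903 libraries. Growing hair follicles may account for part of it, since 22 of the 22 hair follicle genes below the filter were highest in this library. Chance gives about 2.8 for independent genes. These genes were high together, and tested members of the same list had already set this library apart, so the count overstates the evidence. Whether growing hair follicles bear on the lower Cyp24a1 of this library was not tested. Its position between the groups was taken on the FPKM scale, not on log2, for genes at least 2-fold changed and called without it. It lay a median 25.5% of the way to the phytic acid mean for 492 higher genes and 63.1% for 376 lower genes. Without logs such shares come out smaller for rising genes and larger for falling ones, so the difference between these medians is not interpreted. A weaker reaction to MC903 in this sample, or mixing with a sample from outside the series, stays open and was not tested.

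The fall of wound keratinocyte genes with phytic acid could come from dilution by other tissue, from depth or from a weaker response to MC903 itself. Dilution is argued against by the size of the fall. The mean of the wound list fell by 2.467 log2 units relative to that of basal keratinocyte genes (SD 0.414 in MC903 and 0.627 with phytic acid, exact permutation p = 0.0286, the smallest possible). The wound means alone did not overlap (6.56 to 7.68 in MC903, 4.13 to 5.51 with phytic acid), so this p was likely beforehand and adds little. At equal depth, 19 of the 19 called members that could be thinned were still called lower. FPKM is already scaled to the library total, so this outcome was likely beforehand and is weak evidence against depth. A weaker vitamin D receptor response to MC903 is a candidate explanation. Vitamin D response genes without Cyp24a1 changed by a mean of -0.554 log2 units (SD 0.276 and 0.159, exact permutation p = 0.0286). Of these 7 genes, 6 had a negative log2 fold change, and only Spp1 and Trpv6 were called. Trpv6 lost its call without MC903 replicate 1 (adjusted p = 0.0899 by limma) and under other settings. Vdr, the receptor gene, is among the 7 and stood at 43.3 FPKM in MC903 replicate 3 against 18.4 to 21.7 in the other MC903 libraries. With phytic acid it stood at 21.2 to 27.5, so its negative log2 fold change rests on MC903 replicate 3. The exact permutation p of the whole list was 0.0286, the smallest possible, and 0.0914 after adjustment over the lists. No list had a lower adjusted value, and the wound list had the same. The design has no phytic acid without MC903 and no untreated skin, so less MC903 reaching the skin and a damped reaction to it both stay open.

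Skeletal muscle, fat and nerve markers were higher with phytic acid. A lower share of epidermis alone would raise all other cell types alike and is argued against by the sizes of the rises. Relative to the endothelial mean, the muscle mean rose by 1.184 log2 units (exact permutation p = 0.0286) and the nerve mean by 0.532 (exact permutation p = 0.0286). On the same basis the adipocyte mean rose by 1.137 (exact permutation p = 0.0857) and the matrix mean by 0.076 (exact permutation p = 0.714). Muscle and nerve means alone did not overlap between the groups, so their p, the smallest possible, was likely beforehand. A larger share of the same muscle as the whole cause is also argued against: of 14 muscle genes with a mean FPKM of at least 100, 8 lay more than 2 standard errors from their median log2 fold change of 1.10, in a range from 0.45 to 2.94. How deep each piece of skin was cut is not in the labels and may differ between the groups, and a change within the muscle stays open as well.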

How the results depend on the processing

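The limits of this part are those of 4 libraries per group, and voom, thinning to equal depth and basal centring were chosen after the data were seen. The number of called genes was 3134 and stayed within 1.5 times of that under all settings but those named here. It was 4796 (2865 higher) with library weights, and with a mean FPKM of at least 5 there were 1098 higher calls, where fewer genes were tested. Leaving out 1 library at a time gave 2013 to 3979 calls, 1072 to 2418 of them higher and 941 to 1561 lower, with the lowest of each without MC903 replicate 1 and the highest total without MC903 replicate 3. Fewer samples account for part of that drop. Centred on basal keratinocyte genes, 549 genes were lower, and 608 were higher under the lenient limits. The lenient count was 1097 (648 higher) with a pseudocount of 0.01, and 625 were higher with voom on the recovered reads. Lists called were 13 by camera with the preset correlation, 0 with an estimated one, 11 by fry in a single direction and 29 by fry in either direction. The 11 include the aryl hydrocarbon receptor (0.0422), oxidative stress (0.0422) and junction (0.0469) lists, which camera did not call. A smaller pseudocount takes less off the changes of low genes. For library weights, voom and basal centring the cause was not tested. The replicate number as a block gave 2046 calls (1098 higher). Deviations of libraries with the same number correlated at -0.283, -0.105, -0.286 and 0.225. These values give no sign of pairing by number, but so few of them cannot exclude a weaker shared effect. Of the comparisons of single genes and lists with an alternative, 3011 stayed on the same side of the threshold, 136 lost the call, 20 gained it, and 0 calls reversed direction. Medians of lists that were not called changed sign under some settings, such as that of neutrophil markers without MC903 replicate 4 (0.13 against -0.32). The planned edgeR test on recovered reads was not run. Voom on those reads called 2984 genes and thinning to equal depth 3038. In simulated data, with few changed genes and genes drawn independently, 30.1% of 1.5-fold changes were called.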

Other observations

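The gene families below were chosen after their values were seen, and some of their members are in the fixed lists. All 11 Skint genes rose, 11 of 11 tested, with a median log2 fold change of 2.26. Skint1, which is known for its part in the development of the gamma delta T cells of mouse epidermis, went from 8.77 ± 4.51 FPKM (SD, n = 4) to 28.3 ± 5.22, and Skint7 was at or below 1.25 FPKM in each MC903 library and at or above 12.3 in each phytic acid library. Among kallikrein-related peptidases, some of which cut the junctions of shed corneocytes, 8 of 9 fell and 1 rose, with a median of -1.57. Klk13 fell from 161 ± 80.2 to 11.985 ± 2.479 and Klk7 from 1167 ± 307 to 476 ± 46.9, while Klk5 rose from 61.6 ± 14.6 to 94.8 ± 9.82. Of 6 connexin genes of the Gjb family, 4 fell and 1 rose: Gjb2 fell from 282 ± 66.1 to 18.1 ± 11.3 and Gjb6 from 92.4 ± 33.1 to 7.92 ± 3.13, and Gjb5 rose from 14.6 ± 8.95 to 36.1 ± 7.32. Close copies within the Skint family can share reads.

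Class II genes and the Langerhans cell gene Cd207 (langerin) went with Skint genes in direction. Cd207 rose from 2.13 ± 1.88 FPKM (SD, n = 4) to 16.0 ± 6.91 and Ccl27a was 2.15, 4.27, 10.6 and 2.07 in MC903 replicates 1 to 4 and 41.5, 26.4, 26.6 and 42.5 with phytic acid. Retnla, a gene that type 2 cytokines induce in macrophages, rose from 82.4 ± 46.1 to 645 ± 372, while Arg1, another such gene, fell from 80.8 ± 31.7 to 10.4 ± 5.57. In the Serpinb family 6 of 17 rose and 4 fell (median 0.20), and of 6 tested genes of the Mrgpr receptor family 2 rose and 0 fell. Of 3 tested Mup genes 2 rose, with Mup22 between 3.24 and 69.5 in the phytic acid libraries, and of 6 gasdermin genes 1 rose and 2 fell. Of 2 entries without a gene name that passed the filter, 0 were called by limma.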
